A study of Homo sapiens with 3 samples.

How the data were processed

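Gene expression was measured in H2030-BrM3 lung adenocarcinoma cells that carried a non-targeting short hairpin RNA (1 array) or 1 of 2 hairpins against PARP1 (1 array each). Per the labels, the cells were cultured in RPMI 1640 medium with fetal bovine serum, total RNA was isolated with an RNeasy kit, labelled with biotin after amplification with an Illumina TotalPrep kit and hybridized to Illumina HumanHT-12 V4 BeadChips. The deposited non-normalized table holds a bead-averaged intensity per probe, made by the authors with GenomeStudio per the labels, on a linear scale and neither background-subtracted nor equalised between arrays, as the values show. The authors also deposited a detection p-value per probe beside each intensity, per the file headers, which moves in steps of 1 in 770 and so ranks a probe among negative control probes. The second deposited table holds intensity values whose sorted columns were equal between arrays to within 0.706 and whose ranks within an array matched the first table (Spearman's rho of 1), so quantile normalization of the same signals by the authors was inferred from the values, on a linear scale and without background subtraction. Its column medians were each 152.6. The GenomeStudio version, its background setting and its annotation are not given in the sources used here.

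Each array held 47309 probes in the non-normalized table, and 14 more were in the normalized table. Signals ran from 109.2 to 32104, with 35.6%, 34.6% and 36.8% of probes above background on the control, hairpin 1 and hairpin 2 arrays. Probes were named from the platform annotation, whose 1 gene symbol was checked through its gene ID against a RefSeq gene table of assembly GRCh38.p14. That table was used for names only, and no coordinates are given because the files name no genome build. Of the probes, 30106 had 1 gene symbol and 17203 did not, 8 probes were listed with several genes and were not named, 30074 gene IDs were found in the RefSeq table, and 0 symbols had to be updated. 2 entries of the gene lists matched no current gene.

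Background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3 (normal-exponential model fitted through the detection p-values, offset 16, quantile normalization, log2 scale). Probes with a detection p under 0.01 on at least 1 array were kept, and each gene was represented by the probe with the highest mean log2 intensity over all arrays. PARP1 hairpin arrays were compared with the control array in limma (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 10692 genes tested and a threshold of 0.05. The fit has 1 residual degree of freedom per gene, the difference between the hairpins, plus a median of 7.30 prior degrees of freedom borrowed across genes. The lone control array is assumed to vary like the hairpin arrays. Every standard error (SE) of a log2 change is limma's moderated one. It combines a gene's residual variance with the prior variance and is not the spread of the arrays alone. The median of these standard errors was 0.147, which gives a 95% half-width of 0.336.

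Because limma has so little replication here, genes at least 1.5-fold from the control in the same direction with both hairpins were also counted, and the count at 2-fold was added. The counts, the correlation and the covariance of the hairpins' ratios were set beside 1000 simulations of unchanged arrays that share 1 control. These counts and the ranking of genes use measured ratios, probes below the detection threshold on some arrays included. In the text, the fold of a highest or lowest gene with no probe above background in a group is given only as a bound, the mean of the brighter group against the mean of, per array, the higher of its own value and the lowest value among detected probes, which was 5.63, 5.74 and 5.53 on the control, hairpin 1 and hairpin 2 arrays. Lists of genes were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated one, and the median ratio of each list was placed among 10000 random lists of matched intensity. Of 35 lists, 33 had at least 3 measured members and were tested.

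The groups, tests, gene lists, alternatives and naming rule were fixed before the data were examined, apart from those said to be chosen later. The rule named PARP1, S100A4 and CLDN7 always, then the 12 highest and 12 lowest genes of the same sign with both hairpins by the smaller absolute log2 ratio, filling the places from genes that did not pass the test where too few passed. It took up to 4 members of each gene list, and the 5 genes of opposite sign furthest apart each way between the hairpins. Genes with provisional names were to be skipped, and 0 were.

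The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the deposited normalized values, other filters on dim probes, the mean of a gene's probes, other variance priors, other thresholds, an estimated correlation between genes and leaving out each hairpin. The procedure was tested on simulated data for this comparison, with 10692 genes, 50 simulations and 50 changed genes per fold. limma called 22.4% of genes changed 1.5-fold, 65.6% at 2-fold, 90.8% at 4-fold and 92.6% at 8-fold. It made 3.74 false calls on average, and made a call in 3 of 50 simulations where nothing changed. Each simulation with changes held 200 changed genes, and Benjamini-Hochberg adjustment passes a given p more readily when many genes change. The shares called by limma therefore do not hold where few genes differ. Each simulated change also had the same size on both hairpin arrays, so these shares do not hold for genes whose change differs between the hairpins. On the real arrays PARP1, 3.54-fold and 7.75-fold lower, had a limma adjusted p of 0.734. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probes without a single gene symbol were left out of the tests because they could not be named.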

Results

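The data are 3 Illumina HumanHT-12 V4 expression arrays of H2030-BrM3, a derivative of the human lung adenocarcinoma line H2030 that was selected for its ability to form brain metastases. 1 array held RNA from cells carrying a non-targeting short hairpin RNA, the control. The other 2 arrays held RNA from cells carrying hairpin 1 or hairpin 2 against PARP1, the enzyme that senses DNA breaks and builds poly(ADP-ribose) chains on proteins. The series is titled as a search for PARP1 target genes, so the comparison of interest is which transcripts differ when PARP1 is depleted. Each array measured 47309 probes, and the median probe intensity was 153.6 in the control, 152.2 with hairpin 1 and 161.7 with hairpin 2. The probes above background, with a detection p under 0.01, numbered 16855, 16350 and 17420 on these arrays. After filtering, 10692 genes were tested, and 9697 of them (90.7%) were above background on all 3 arrays. The control was a single array, and the hairpin arrays carried different hairpins, so the only spread that could be measured was the difference between 2 hairpins. Nothing in the labels says that the arrays came from separate cultures, and p-values here measure only the spread between these samples, which may be technical. All 3 arrays lay on 1 BeadChip, and the small number of arrays limits the precision of every value.

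PARP1 itself was lower with both hairpins (probe ILMN_1686871, the only probe named PARP1). Its normalized log2 intensity was 12.11 in the control, 10.29 with hairpin 1 and 9.15 with hairpin 2. The transcript was left at 28.2% of the control with hairpin 1 and at 12.9% with hairpin 2. Before normalization the probe gave intensities of 4365, 1312 and 765.8. The mean log2 change over both hairpins was −2.39 ± 0.36 (moderated SE, n = 2 against 1), with an unadjusted limma p of 0.000137 and an adjusted p of 0.734 over all genes. No other gene had a lower ratio with either hairpin. The hairpins differed from each other by −1.13 on the log2 scale (hairpin 2 minus hairpin 1). PARP1 was tested against this gap combined with the prior variance borrowed across genes. With median scaling in place of quantile normalization the limma adjusted p of PARP1 was 4.65e-27. That setting took each gene's variance from the intensity trend alone, so the gap between the hairpins for PARP1 did not enter the test. With the mean of a gene's probes the limma adjusted p of PARP1 was 0.00725, and in the other settings it lay between 0.162 and 0.995. As PARP1 has 1 probe, its log2 change was the same with the mean of a gene's probes. The prior degrees of freedom borrowed across genes were then 13.3 instead of 7.30.

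S100A4, CLDN7 and CTBP2 were also lower with both hairpins. S100A4, a calcium-binding protein linked to cell motility and metastasis, had log2 ratios to the control of −0.45 with hairpin 1 and −0.51 with hairpin 2, a mean 1.39-fold lower. A second S100A4 probe gave −0.63 and −0.55. CLDN7, a tight junction claudin, had log2 ratios of −1.14 and −0.81, a mean 1.97-fold lower, but its mean log2 change was only −0.47 without background correction and −0.46 on the deposited normalized values. CTBP2, a transcriptional corepressor, had log2 ratios of −1.15 and −1.55 by its brightest probe, a mean 2.54-fold lower, but only −0.40 and −0.13 by another probe above background on all 3 arrays. The unadjusted limma p was 0.00454 for S100A4 (mean log2 change −0.48 ± 0.12, SE), 0.00265 for CLDN7 (−0.98 ± 0.23) and 8.84e-05 for CTBP2 (−1.35 ± 0.19). None of these passed the adjustment over all genes, where the limma adjusted p was 0.994, 0.994 and 0.734. S100A4 and CLDN7 were named in advance because the study is known to have followed them up, so their direction is not independent evidence. The log2 change of CTBP2 was −1.27 with median scaling (limma adjusted p = 0.000154), −0.81 with the mean of its probes (0.731), −0.93 without background correction (0.687) and −0.89 on the deposited normalized values (0.245). The low adjusted p with median scaling again took no account of the gene's own difference between the hairpins.

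**Figure D1:**
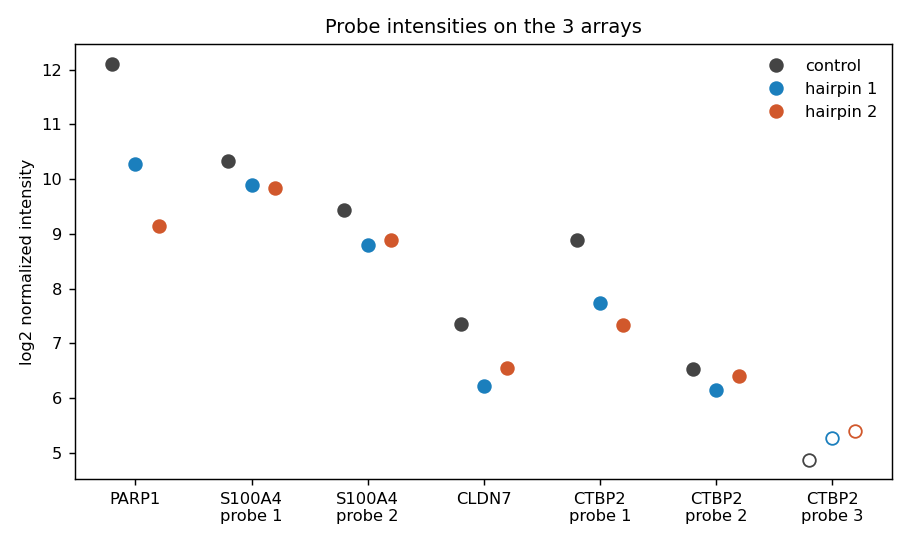
Normalized log2 intensity (y axis) of each PARP1, S100A4, CLDN7 and CTBP2 probe on the control array and the 2 hairpin arrays, 1 point per array with no replicate arrays and so no error bars; filled points had a detection p under 0.01 and open points did not. PARP1 lies at 12.11 in the control and at 10.29 and 9.15 with the hairpins. The CTBP2 probes with filled points differ in how far the hairpin arrays lie below the control. The CTBP2 probe with open points lies above the control with both hairpins.

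No gene passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and the smallest adjusted p was 0.734. At an unadjusted limma p under 0.05 there were 376 genes, 190 higher and 186 lower, where chance alone gives 534.6. By a rule of size alone, 104 genes differed at least 1.5-fold from the control in the same direction with both hairpins, 39 higher and 65 lower. Of these, 21 were above background on all 3 arrays, 9 higher and 12 lower. At 2-fold the rule held 9 genes, 2 higher and 7 lower, of which only PARP1 and CTBP2 were above background throughout. Without background correction, or on the deposited normalized values, the 1.5-fold rule held only PARP1 and CTBP2.

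The 12 highest genes by the smaller of their ratios were all below the detection threshold in the control, so their differences are bounds. They entered the test only through the hairpin arrays, where they were high, and were then picked as extremes. The bounds take no account of noise between arrays and apply to the main background correction only. For IFIT2 the mean log2 change was 0.32 without background correction and 0.34 on the deposited normalized values. IFIT2, an interferon-induced gene, was at least 1.68-fold higher. NDNF, a secreted neurotrophic factor, was at least 1.56-fold higher, and BRSK2, a brain-enriched kinase, at least 1.46-fold. FAM133A was at least 1.42-fold higher. MMP15, a membrane-type matrix metalloproteinase, was at least 1.39-fold higher, and IL13RA2, a decoy receptor for interleukin 13, at least 1.34-fold. The bounds were 1.36-fold for AP3B2, 1.23-fold for BCL2L14, 1.22-fold for MIR9-1HG and 1.01-fold for both FGFR4 and ZFP14. MIR342 gave no bound above 1-fold. Another probe of BCL2L14 went the other way with both hairpins but was not above background on any array, so it gives no fold. The limma adjusted p was 0.994 for each of these 12.

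The 12 lowest genes were PARP1, CTBP2, AP5B1 and 9 genes not above background with either hairpin. AP5B1, a subunit of the AP-5 adaptor complex, had log2 ratios of −1.14 and −1.24 (mean −1.19 ± 0.28, SE) and was above background on 2 arrays. Its mean log2 change was −0.44 without background correction and −0.45 on the deposited normalized values. The other 9 entered the test only through the control array, and for them the difference is again a bound with the same limits. ACP4 was at least 1.33-fold lower, KCNJ18 at least 1.25-fold, and both RAET1E, a ligand of the NKG2D receptor, and LINC02875 at least 1.24-fold. FBXL19 and OR2T11 were at least 1.22-fold lower. BACH2, a transcriptional repressor of lymphocytes, was at least 1.09-fold lower, ERCC4, a nuclease of nucleotide excision repair, at least 1.04-fold and VAV1, an exchange factor of blood cells, at least 1.02-fold. A second ERCC4 probe went the other way with both hairpins but was not above background on any array.

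When the same ranking was applied to the genes above background on all 3 arrays, a list drawn up after the values had been seen, RNF122 was the highest, with log2 ratios of 1.02 and 0.73. It was followed by TRMT44 (0.69 and 0.69), the potassium channel subunit KCNMB3 (0.68 and 0.96) and AMT, an enzyme of the glycine cleavage system (0.67 and 0.72). The brightest of the higher genes was RBM26, an RNA-binding protein, with a mean log2 change of 0.70 ± 0.14. CREM, a cyclic AMP responsive transcription factor, had log2 ratios of 0.64 and 0.76, and CDH10, a cadherin, 0.84 and 0.62. Below PARP1 and CTBP2, the lowest were SMIM10L2B (−0.82 and −0.93), CLDN7 and C15orf40 (−0.75 and −0.77). The splicing regulator MBNL2 had log2 ratios of −0.63 and −0.80 by its brightest probe, while another probe, not above background with hairpin 1, gave −0.13 with hairpin 2. The transcription factor USF2 had −0.60 and −0.63 by its brightest probe but −0.07 and −0.12 by another bright probe. Other probes of TRMT44, SMIM10L2B and MBNL2 went the other way with both hairpins but were not above background on any array. The limma adjusted p was 0.995 for each of these genes when only genes above background on all 3 arrays were tested.

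**Figure D2:**
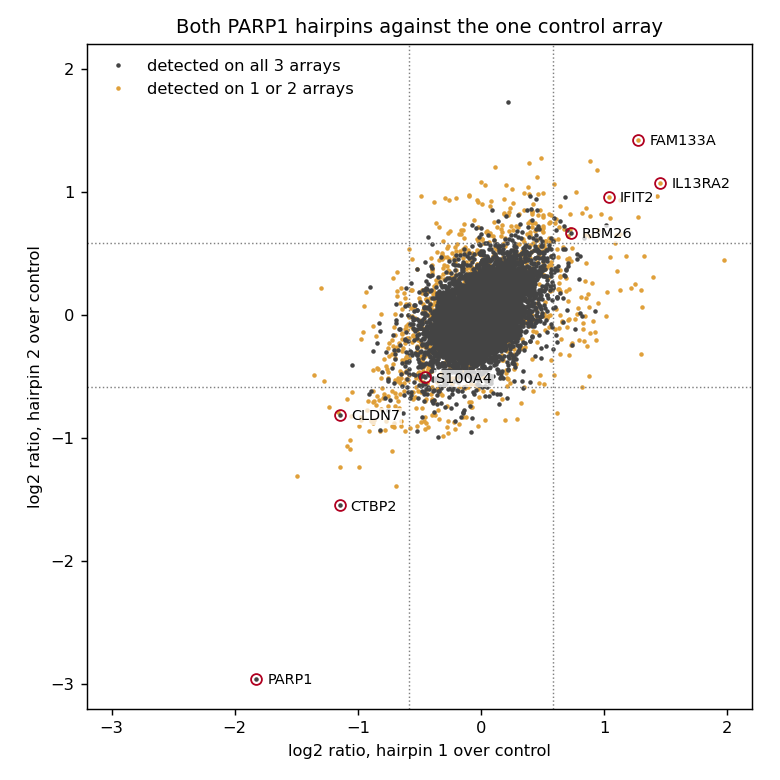
Log2 ratio of each of the 10692 genes tested with hairpin 1 over the control (x axis) and with hairpin 2 over the control (y axis), 1 point per gene, dark where the probe was above background on all 3 arrays and light where it was on 1 or 2; dotted lines mark 1.5-fold. Measured ratios are plotted, so light points include values below the detection threshold. PARP1 lies apart from all other genes at −1.82 and −2.95, and most genes past 1.5-fold with both hairpins are light points.

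PARP1 lay apart from all other genes, and across all genes the correlation and covariance of the hairpins lay within the range simulated for arrays with a common control. Across the 10692 genes the log2 ratios of the hairpins correlated with a Pearson's r of 0.487 and a Spearman's rho of 0.438, where genes are not independent replicates. Both ratios use the same control array, and unchanged arrays simulated against 1 shared control gave an r of 0.500 (central 95% from 0.480 to 0.519). The covariance was 0.0291 against a simulated 0.0308 (0.0289 to 0.0326), a difference of −0.00164. The 2 ratios had the same sign in 65.2% of genes, against 66.4% (65.6% to 67.3%) in the simulation, just below that range. The simulation gave 98.9 genes (81 to 118) past 1.5-fold with both hairpins against the 104 observed, with 49.4 lower (37 to 63) against 65, just above that range, and 49.4 higher (36 to 64) against 39. At 2-fold it gave 8.55 genes (3 to 15) against 9. Lists of independent genes would have shared 2.61 higher and 3.29 lower genes. The single control could not be split, so part of the overlap may come from the shared control. The simulated noise was taken from the difference between the hairpin arrays, which holds any effect of 1 hairpin alone, and it assumes a control array no noisier than these, so the counts expected by chance can be lower or higher than simulated.

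Each array was also set against the other 2 in turn. CCNA1, a cyclin known best from male germ cells, was the 1 gene called when the hairpin 1 array stood alone, with log2 ratios to the control of −0.90 for hairpin 1 and 0.22 for hairpin 2. CD55, a complement regulator of the cell surface, was the 1 gene called when the hairpin 2 array stood alone, with log2 ratios of 0.22 and 1.73. With the control array alone limma called 0 genes, with 376 at an unadjusted p under 0.05, against 471 and 690 for the hairpin 1 and hairpin 2 arrays. The number of genes at least 1.5-fold from both other arrays in the same direction was 104 for the control, 95 for hairpin 1 and 110 for hairpin 2. The SD of the log2 difference across genes was 0.240 between the control and hairpin 1, 0.249 between the control and hairpin 2 and 0.248 between the hairpins.

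The hairpin arrays differed from each other in CD55 and CCNA1 as well as in PARP1. At least 2-fold apart between the hairpins were 47 genes, 22 higher and 25 lower with hairpin 2, and 4 of them were above background on all 3 arrays. These 4 were PARP1, CD55, CCNA1 and the pseudogene PMS2P2, which had log2 ratios to the control of −0.43 with hairpin 1 and 0.63 with hairpin 2. At 1.5-fold there were 377 genes, 202 higher and 175 lower with hairpin 2, of which 147 were above background throughout. Among genes of opposite sign, those whose measured values lay furthest toward hairpin 2 were MAL2, MIR574, LINC02396, TARM1 and TRPM7. Those furthest toward hairpin 1 were KRTAP10-2, SUCLG2-DT, SPARCL1, WASHC2C and SCARNA9L. None of these genes of opposite sign was above background on all 3 arrays, so their order rests partly on signal below the detection threshold and no ratios are given. Neither hairpin had a replicate array, so no test of their difference was made.

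Of 8 measured S100 genes, 6 were lower with both hairpins and 2 were higher with both. As a list they passed the test with a preset correlation between genes (adjusted p = 0.0404 in limma's camera) but not with an estimated one (adjusted p = 0.946). S100A4 had log2 ratios of −0.45 and −0.51, S100A6 had −0.11 and −0.17, S100A16 had −0.98 and −0.20 and S100A14 had −0.70 and −0.17, the last pair being above background on 2 arrays only. S100A13 (0.10 and 0.04) and S100A9 (0.03 and 0.04) were the higher members. The median log2 ratio of the list was −0.20 with hairpin 1 and −0.13 with hairpin 2, at percentiles 0.16 and 4.08 of 10000 random lists of matched intensity. With the preset correlation it was the only one of 33 lists past the threshold. The estimated correlation and its camera test rest on 1 residual degree of freedom, where the smallest unadjusted p of any list was 0.185. Failing that test is therefore no evidence for or against a list. The call was also lost without S100A4 (adjusted p = 0.192, chosen after seeing the data), on the deposited normalized values (0.0505) and with all 3 other filters on dim probes (0.184 to 0.504). Over 9 processing settings the adjusted p ranged from 0.000285 to 0.504, and 5 lay past the threshold. With the hairpin 1 array standing alone, the other arrays were higher at an unadjusted camera p in limma of 0.00174, against 0.00122 for the control standing alone. S100A4, which the study followed up, is a member, so the list is not fully independent evidence.

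4 further lists had an unadjusted camera p under 0.05 in limma, each with an adjusted p of 0.192. Of 15 TGF-beta and BMP target genes, 7 were lower with both hairpins and 2 higher, with medians of −0.12 and −0.15. ID1, an inhibitor of differentiation induced by BMP signals, had log2 ratios of −0.35 and −0.27, SKIL −0.36 and −0.20, JUNB −0.42 and −0.20 and the feedback inhibitor SMAD7 −0.44 and −0.17. Of 8 epithelial markers 4 were lower and 1 higher, among them the transcription factor OVOL2 (−0.39 and −0.36) and the keratin KRT18 (−0.18 and −0.27). Of 20 hypoxia and glycolysis genes 11 were lower and 3 higher. They included ANKRD37 (−0.28 and −0.51), the glucose transporter SLC2A1 (−0.39 and −0.17) and NDRG1 (−0.52 and −0.16). Of 17 cholesterol synthesis genes 10 were higher and 3 lower, with medians of 0.14 and 0.03. INSIG1, a sterol sensor partner, had log2 ratios of 0.36 and 0.46, HSD17B7 0.25 and 0.26 and HMGCS1 0.17 and 0.21. With an estimated correlation, on 1 residual degree of freedom, no list passed and the smallest adjusted camera p in limma was 0.946. That test decides nothing about these lists.

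Among the genes nearest to PARP1 in function, no list stood apart. Of 14 measured members of the PARP family and of ADP-ribose turnover, PARP1 was the only one at least 1.5-fold from the control, with PARP2 at 0.12 and 0.04, PARP3 at 0.07 and 0.11, PARP12 at −0.16 and −0.13 and PARP16 at −0.15 and −0.21. The list's adjusted camera p in limma was 0.527, and with median scaling it was 0.000802. The depleted gene PARP1 is itself a member of the list. With the main processing the list's mean log2 change was −0.19 and its median −0.02. The call with median scaling is therefore not evidence on the other members. Of 14 homologous recombination genes 7 were higher with both hairpins and 3 lower, at an adjusted camera p of 0.527. The higher ones included BRCA1 (0.23 and 0.28) and XRCC2 (0.26 and 0.22). Of 6 non-homologous end joining genes 3 were higher and 0 lower, at the same adjusted p of 0.527. Base excision and single-strand break repair genes split 7 higher to 5 lower of 19 (adjusted p = 0.724), with OGG1 at −0.21 and −0.39. Of 12 NAD metabolism genes 3 were higher and 4 lower (0.655), and SIRT7 had log2 ratios of 0.37 and 0.29. All 16 measured p53 target genes kept 1 sign with both hairpins, 8 higher and 8 lower (0.932), with FAS at −0.67 and −0.29, CDKN1A at −0.30 and −0.19 and SESN1 at 0.38 and 0.31.

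No list of adhesion, invasion or metastasis genes passed the test. CLDN1 was higher (0.48 and 0.37, mean 0.43 ± 0.11, SE) where CLDN7 was lower, and the claudin and tight junction list split 4 to 4 of 10, with an adjusted camera p in limma of 0.953. Adjusted over the list alone, 4 genes passed 0.05 in limma in all lists together, against 0 adjusted over all genes tested. They were PARP1 (0.00192), S100A4 (0.0363), CLDN7 (0.0223) and CLDN1 (0.0223). PARP1 was the depleted gene, and for S100A4 and CLDN7 this is not independent evidence. These values were not adjusted for the number of lists. Of 15 matrix proteases and invasion genes 3 were higher and 5 lower (adjusted p = 0.622), with the urokinase receptor PLAUR at −0.42 and −0.60. Of 11 mesenchymal markers 4 were higher and 3 lower (0.692), with TWIST1 at −0.41 and −0.37. Of 8 integrins 2 were higher and 1 lower (0.623), with ITGA5 at 0.32 and 0.41. Of 9 measured genes tied to brain metastasis in earlier studies of related lines 4 were higher and 1 lower (0.527), with PTGS2 at 0.37 and 0.34 and ANGPTL4 at −0.13 and −0.17. Of 13 angiogenic and secreted factors 3 were higher and 3 lower (0.724).

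Signalling and stress lists also showed no shift that passed the test. Of 18 interferon-stimulated genes 9 were higher and 3 lower (adjusted camera p in limma 0.527), with IFIH1 at 0.51 and 0.41 and XAF1 at −0.31 and −0.30. Of 14 NF-kB target genes 3 were higher and 7 lower (0.692), with CXCL2 at −0.61 and −0.30. Of 19 genes of the unfolded protein response and ATF4 11 were higher and 2 lower (0.477), with TRIB3 at 0.33 and 0.19. Of 13 heat shock genes 8 were higher and 2 lower (0.527). Of 19 NRF2 target genes 2 were higher and 6 lower (0.623), although ME1 had log2 ratios of 0.36 and 0.56. Of 15 stem cell and self-renewal genes 3 were higher and 6 lower (0.560), with KLF4 at −0.56 and −0.33.

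Proliferation and housekeeping lists lay near the control. Of 22 G1/S and DNA replication genes 10 were higher and 4 lower (adjusted camera p in limma 0.560), with MCM3 at 0.19 and 0.19. Of 24 G2/M and mitosis genes 8 were higher and 12 lower (0.885), and their mean (0.02) and the test pointed up while their median (−0.02) pointed down. Of 18 apoptosis and survival genes 7 were higher and 7 lower (0.932), with BAK1 at 0.31 and 0.29 and CFLAR at −0.24 and −0.30. The adjusted p was 0.932 for 21 oxidative phosphorylation genes and 16 core histones, 0.724 for 19 cytosolic ribosomal protein genes and 0.735 for 14 housekeeping genes. The median of the claudin list (0.01) differed in sign from its mean (−0.03) and test.

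Markers of other cell types were mostly not above background. None of 10 endothelial markers and 1 of 16 alveolar and airway markers could be measured, the latter being FOXA2 (−0.16 and −0.15), so these lists were not tested. Of 4 measured fibroblast markers 2 were higher and 1 lower (adjusted camera p in limma 0.724), with PDGFRA not above background in the control and at least 1.19-fold higher with the hairpins. For 3 leukocyte markers the adjusted p was 0.932, with a median (0.02) above 0 and a mean (−0.00355) below it. For 4 markers of neurons and glia it was 0.803.

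**Figure D3:**
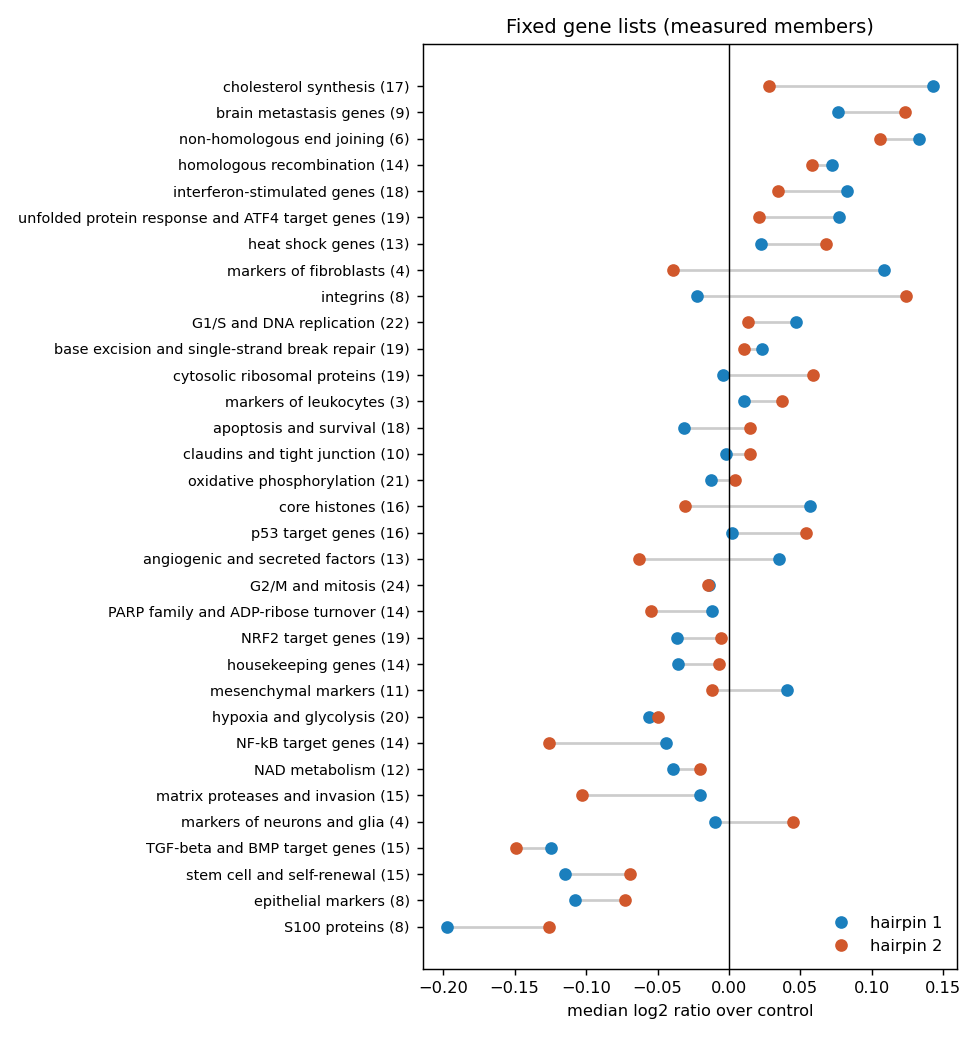
Median log2 ratio over the control (x axis) of the measured members of each of the 33 gene lists tested, with 1 point for each hairpin and the number of measured members in parentheses. The S100 list lies lowest with hairpin 1, at −0.20, and at −0.13 with hairpin 2, and the cholesterol synthesis list lies at 0.14 and 0.03.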

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

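The tests of the S100 list without S100A4 and with a hairpin array standing alone, and the 1.5-fold counts with a hairpin array standing alone, were chosen only after seeing the data. PARP1 was lower under each of 11 settings (log2 change from −2.40 to −2.19, unadjusted limma p up to 0.00829), at −2.95 and −1.82 with 1 hairpin left out. The limma count of 0 genes became 3 with median scaling (CD55, CTBP2 at −1.27 and PARP1) and 1 with the mean of a gene's probes (PARP1). Median scaling left the median log2 ratio of all genes at 0.136 with hairpin 2 and took each gene's variance from the intensity trend alone. It also gave 2 lists past the threshold, the PARP family list among them (adjusted p = 0.000802). The count of 104 genes past 1.5-fold with both hairpins was 2 without background correction, 11 with an offset of 50, 2 on the authors' values, 21 with detection on all 3 arrays, 158 without a filter and 9 at 2-fold. It was 333 to 379 with 1 hairpin left out, when only 1 ratio has to pass, and 95 and 110 with a hairpin array standing alone. The 377 genes 1.5-fold apart between the hairpins became 12, 75, 8, 147 and 617 under the first 5 of these settings, and 578 with a detection p under 0.05. The correlation of the hairpins was 0.472 with detection on all 3 arrays and lay between that and 0.497 over 9 settings.

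The S100 list kept its direction, but its adjusted p was 0.0505 on the authors' values, 0.184 with detection on all 3 arrays, 0.233 with a detection p under 0.05, 0.504 without a filter and 0.946 with an estimated correlation, each leaving 0 lists past the threshold. Without S100A4 it was 0.192. With the hairpin 1 or hairpin 2 array standing alone it was 0.0575 or 0.96. The test with an estimated correlation had 1 residual degree of freedom, so its loss of the call decides nothing. The lists were on the same side of the threshold in 323 of 329 pairs of list and setting, and 14 pairs, none of a called list, pointed the other way. Of 253 pairs of named gene and setting, 251 kept their direction. ERCC4 turned to 0.26 with a detection p under 0.05 and without a filter, since its other probe then became the brightest. Apart from these, the cause was not tested. No paired analysis was possible because there was only 1 control array. Leaving out a hairpin leaves no residual degrees of freedom, so no limma or list test was run there. Signal over background limits the fold counts: 21 of the 104 genes were above background on all 3 arrays.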

Other observations

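The tests of the 1.5-fold counts, the CTBP2 probes, other splits of the arrays, the S100 list without S100A4 or with a hairpin array standing alone, small RNA genes and the size of change were chosen only after the data had been seen. Among 126 small nucleolar, Cajal body and Y RNA genes, 41 were higher and 37 lower with both hairpins. Their median log2 ratios were 0.01 and 0.02. The Y RNA gene RNY1 had log2 ratios of 0.56 and 0.63, which prompted the hypothesis that such small RNA genes were higher as a class. limma's camera test gave an unadjusted p of 0.789 with the direction down, so the hypothesis was not borne out. Of the probes without a gene name, 2951 were above background on all 3 arrays, and 5 were at least 1.5-fold higher and 5 at least 1.5-fold lower with both hairpins, none at 2-fold.

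A second hypothesis was that genes responding to PARP1 would differ more from the control with hairpin 2, which left less PARP1. Of the 20 genes other than PARP1 that were above background on all 3 arrays and past 1.5-fold with both hairpins, 11 had the larger ratio with hairpin 2 (exact two-sided binomial p = 0.824). Genes are not independent replicates, and the count leaves the hypothesis undecided.

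The 104 genes past 1.5-fold with both hairpins were weighed as an effect of PARP1 depletion, as noise of the single control array and as signal near background. Noise of the control array may account for most of them, since taking a hairpin array as the lone array gave up to 110 genes. Weak signal may account for them as well, because 20.2% of them (Wilson 95% interval 13.6% to 28.9%) were above background on all 3 arrays, against 90.7% of all genes tested. A shared effect of PARP1 depletion stays open, as the covariance of the hairpins' ratios, 0.0291, lay within the simulated range of 0.0289 to 0.0326. For the limma calls, the real split gave 0 genes and the highest other gave 1, and 3 splits are too few to reach a share under 0.05.

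The lower S100 list was weighed as the effect of S100A4 alone, of probes near background and of which array stands alone. Without S100A4 the mean log2 change of the members went from −0.23 (SD 0.245, 8 genes) to −0.19 (SD 0.240, 7 genes). The call ended (limma camera adjusted p from 0.0404 to 0.192), while the unadjusted camera p was 0.0177. Among genes above background on all 3 arrays the mean was −0.13 (SD 0.196, 6 genes). There the call ended too (adjusted p = 0.184), while the unadjusted camera p was 0.00824. In both tests fewer members with a smaller mean were left. Both unadjusted p-values lay under 0.05, but at a preset correlation that was assumed and that these arrays could not check. With an estimated correlation the full list had an unadjusted camera p of 0.185. That test has 1 residual degree of freedom, so no conclusion is drawn from it. The 2 tests rest on the assumed correlation and so cannot decide whether S100A4 alone or dim probes alone were the cause. Each test also kept members that the other removed, so S100A4 and dim probes together stay open as a cause. With the hairpin 1 array standing alone the list gave an unadjusted p of 0.00174, with the other arrays higher, so an oddity of the hairpin 1 array may contribute and cannot be told apart from an effect of depletion with 3 arrays. A response of S100 genes to PARP1 depletion is therefore a hypothesis that replicate control arrays could test.

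Among genes above background on all 3 arrays CTBP2 was nearest to PARP1 in size, and it may be a difference seen by 1 probe only. Its other probe above background on all 3 arrays had a mean log2 ratio of −0.265 (−0.40 and −0.13), against −1.35 by the brightest probe. The remaining probe went the other way with both hairpins but was not above background on any array. A change in 1 CTBP2 transcript form and an artefact of 1 probe both remain open, since which transcripts each probe reads was not analysed here.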
